A study of Mus musculus with 12 samples.

How the data were processed

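RNA for 12 libraries of mouse bone-marrow-derived dendritic cells (C57BL/6, per the labels) was extracted with TRIzol and a column kit, prepared with an unstranded kit and sequenced on a HiSeq 2000, per the labels' protocols. The labels give curdlan at 200 mg/ml for 3 hours, a unit that could not be checked here. The deposited counts are whole numbers of reads per gene and library, not normalized. Per the submitters' processing notes, the tools were FastQC 0.11.1, TopHat2 with the version written as 2.4.2a, SAMtools 1.2, featureCounts 1.4.6 and DESeq2 1.8.2. The genome build, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The authors also deposited a table of KO against WT with curdlan and a table named an interaction, each with log2 fold changes and their standard errors, per the file headers. The same deposited tables hold p-values and adjusted p-values, which the file headers and the processing notes tie to DESeq2. The model behind them is not given in the sources used here. The 18 columns of normalized values per library in these tables were not used.

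Genes are named by the symbols in the authors' files, which cover 33170 of 37991 genes; the other 4821 carry an identifier alone, and 10118 genes had no read. Coordinates and gene types are those of GENCODE mouse release M21 (GRCm38), matched by Ensembl identifier, and 1393 tested genes had no match. Groups follow the labels, and replicate numbers follow the library names. Sample titles number the libraries of each group from 1 to 3 in another way. In the authors' comparison table the 3 WT curdlan columns carry the numbers 4, 1 and 2 where the count table gives identical columns the numbers 1, 2 and 4, so the 2 sources disagree on those numbers. Replicates of a group differed by more than counting noise, with chi-square per degree of freedom from 9.92 to 84.1, and none were merged.

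From the counts, 18981 genes passed edgeR's filterByExpr by group. Libraries were scaled by TMM factors, whose group means were 1.13 (WT unstimulated), 1.03 (WT curdlan), 0.995 (KO unstimulated) and 0.867 (KO curdlan). The 10 most abundant genes held 7.61% to 8.7% of counts by group mean. CPM values use the effective library sizes and are given as mean ± SD. Changes were tested with edgeR 4.0.16 (quasi-likelihood F-test, two-sided) under R 4.3.3, in 1 fit of all 12 libraries with 4 group means, and Benjamini-Hochberg adjusted p-values under 0.05 were taken as past the threshold. The 5 contrasts were curdlan in WT, curdlan in KO, their difference, and KO against WT in each state. The test on the counts of the groups, the lists, the rule for named genes and all alternatives but 2 were fixed before the data were examined.

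Gene lists were tested with limma 3.58.1 (camera, two-sided, preset inter-gene correlation 0.01, Benjamini-Hochberg adjustment over the 32 lists of a comparison), and again with an estimated correlation. The test fry asked separately whether each list moved on balance one way, without comparing it with other genes. Of the 20 gene lists, those reported here covered inflammatory cytokines, chemokines, NF-kB subunits and targets, immediate-early and NFAT-linked genes, MAPK phosphatases and feedback, the C-type lectin receptor pathway, the type I interferon response, eicosanoid synthesis, and glycolysis and hypoxia. They further covered dendritic cell maturation, antigen presentation, NADPH oxidase and antioxidant genes, the inflammasome, sterol synthesis and LXR targets, the stress response and amino acid transport, the lysosome and phagosome, integrins and adhesion, the cell cycle, and ribosomal proteins. The 12 marker lists covered macrophages, conventional and plasmacytoid dendritic cells, neutrophils, mast cells and basophils, eosinophils, T cells, B cells, NK cells, erythroid and megakaryocyte cells, stromal cells and osteoclasts, and sex-linked genes. A further gene list and a B cell marker, both part of the tests, are not reported here. Some macrophage, neutrophil and dendritic cell markers are also expressed by cultured marrow cells.

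Named genes are Vav1, Vav2 and Vav3 in every library, and 22 genes of the Dectin-1 response. They also include, per comparison, up to 10 rises and 10 falls by size among genes past the threshold whose groups did not overlap, with a mean log2 CPM of at least 2 and a symbol not of a predicted gene, and up to 4 members per list by size. Fewer may be given, and a few whose call was lost when a library was left out were passed over for the next in size. Folds against a group without a count use a floor of 3 counts over the group (0.018 to 0.0219 CPM), and low counts given as ratios carry exact 95% intervals. The share of the WT response seen in KO is the summed log2 change over genes changed at least 2-fold in WT, with no test.

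Replicate numbers of the library names were tested as a pairing by correlating deviations from the group means between the states. In WT the 3 pairs gave 0.39, 0.24 and 0.13, so that a fit with replicate number as a block is given beside WT results and the difference of responses where it changes a call. The libraries labelled KO share only 2 numbers between the states (0.29 and 0.56). With that block KO unstimulated 1 and KO curdlan 4 have no partner and carry no weight in the KO response or the difference of responses. The numbers of the sample titles pair all 3 libraries labelled KO (0.22, 0.25 and 0.56) and give the same WT pairs, so that a block by title is given too. Where the pairing comes from is not stated by the labels.

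Alternatives were other scaling factors (RLE, upper quartile), no filter and a stricter filter (1 CPM in 3 libraries), DESeq2 1.42.0, limma voom with sample weights, robust quasi-likelihood, a fit of only the 2 groups compared, the replicate block by library name and by title, a minimum log2 change of 1, and each library left out. Added after seeing the data were scaling by library size alone and a block by the numbers of the authors' comparison table. Simulated counts for 18731 genes with known changes were tested first. In the WT comparison edgeR recovered 56.7%, 100% and 100% of genes changed 1.5-, 2- and 4-fold with 3 false calls, and for the difference of responses 20.9%, 80.6% and 100% with 7 false calls. For KO against WT with curdlan it recovered 59.7%, 97% and 100% with 8 false calls. Overlaps between comparisons that share libraries are set beside 5 simulations of unchanged groups.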

Results

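RNA was sequenced from cultured mouse bone-marrow-derived dendritic cells, antigen-presenting cells grown from marrow progenitors. The cells came from wild-type (WT) mice and from mice labelled as knockouts (KO) of Vav1, Vav2 and Vav3. Vav proteins are signalling proteins that act downstream of Syk-coupled receptors. Cells of each genotype were left unstimulated or were given curdlan for 3 hours. Curdlan is a particulate beta-glucan bound by Dectin-1, the receptor encoded by Clec7a. The comparisons ask which transcripts curdlan changed in each genotype, whether the responses differed, and how the genotypes differed in each state. The 4 groups held 3 libraries each, named here by the numbers in the library names. These were WT 1, 2 and 4 in both states, KO 1, 2 and 5 without curdlan, and KO 2, 4 and 5 with curdlan. Library totals ran from 41421718 to 61217861 counts. Of 37991 genes, 18981 passed the filter on low counts and held at least 99.97% of the counts in every library.

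The genotype label separated the libraries along the first principal component, which held 67% of the variance. Libraries labelled WT lay at -47.48 or lower and libraries labelled KO at 50.13 or higher. Curdlan separated them along the second component, with 14.1% of the variance. Each group had its own sequencing lane (5, 6, 7 or 8), so group and lane cannot be told apart. The labels do not say if replicates came from separate animals or cultures. The p-values measure the spread between libraries, which in WT recurred by number across lanes (6 of 6), arguing against a purely technical one.

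**Figure D1:**
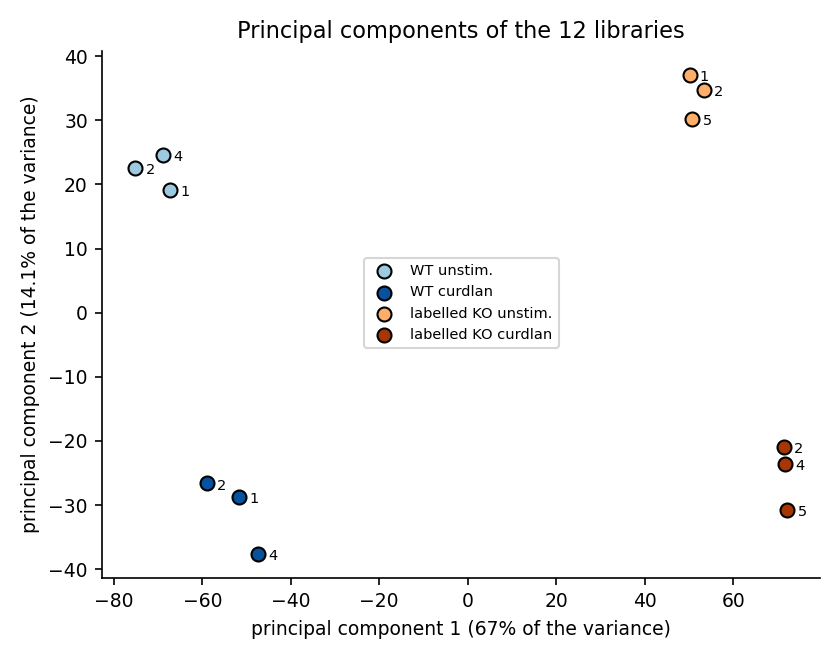
Principal components 1 (horizontal axis, 67% of variance) and 2 (vertical axis, 14.1%) of log2 CPM over the tested genes, without units, with each point a library marked by group and replicate number. The genotype label separates the libraries horizontally and curdlan separates them vertically.

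None of the targeted genes was lower past the threshold in the libraries labelled KO. Vav2 (ENSMUSG00000009621, GRCm38 chromosome 2, 27262104 to 27427033, minus strand) lay at 67.3 ± 3.1 CPM (SD, n = 3) in unstimulated WT cells and at 282 ± 6 CPM in unstimulated libraries labelled KO. With curdlan it lay at 69.3 ± 3.4 CPM in WT and 287 ± 33 CPM in the libraries labelled KO. Vav1 (ENSMUSG00000034116, chromosome 17, 57279100 to 57328031, plus strand) lay at 133 ± 2.2 and 212 ± 18 CPM without curdlan and at 178 ± 1.1 and 276 ± 47 CPM with it, WT given before KO. For Vav3 (ENSMUSG00000033721, chromosome 3, 109340653 to 109685698, plus strand) the values were 26.3 ± 4 and 36.6 ± 4.5 CPM without curdlan and 32.6 ± 4.3 and 28.5 ± 5.1 CPM with it. All 3 genes are annotated as protein-coding, and the counts cover whole genes, so reads from exons inside and outside a deletion cannot be separated.

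Library by library, Vav1 measured 135, 131 and 133 CPM in unstimulated WT libraries 1, 2 and 4, and 179, 178 and 177 CPM in the same numbers with curdlan. In unstimulated libraries labelled KO (1, 2 and 5) it measured 198, 232 and 205 CPM, and with curdlan (2, 4 and 5) 252, 330 and 246 CPM. Vav2 measured 66.1, 70.8 and 65 CPM, then 66, 72.7 and 69.2 CPM in WT without and with curdlan. The libraries labelled KO held 276, 285 and 287 CPM of Vav2 without curdlan and 265, 325 and 270 CPM with it. Vav3 measured 21.6, 28.9 and 28.3 CPM in unstimulated WT and 28.3, 32.6 and 36.9 CPM with curdlan. The libraries labelled KO held 38.3, 31.5 and 40 CPM of Vav3 without curdlan and 30.2, 22.7 and 32.5 CPM with it.

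In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Vav2 was higher in unstimulated libraries labelled KO by a log2 fold change of 2.07 (SE 0.08, adjusted p = 7.45e-09) and with curdlan by 2.05 (adjusted p = 9.26e-09). Vav1 was higher by 0.67 without curdlan (SE 0.1, adjusted p = 0.00021) and by 0.63 with it (adjusted p = 0.000289). Vav3 was higher by 0.48 without curdlan (SE 0.15, adjusted p = 0.0225), a call lost without WT unstimulated 1 (adjusted p = 0.0936) or either of KO unstimulated 1 and 5, and lost when libraries were scaled by size alone (adjusted p = 0.11). With curdlan its log2 fold change was -0.19 (adjusted p = 0.315). No library labelled KO lacked any of the 3 transcripts. The groups are called by their labels throughout, and each direction between genotypes below rests on those labels.

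**Figure D2:**
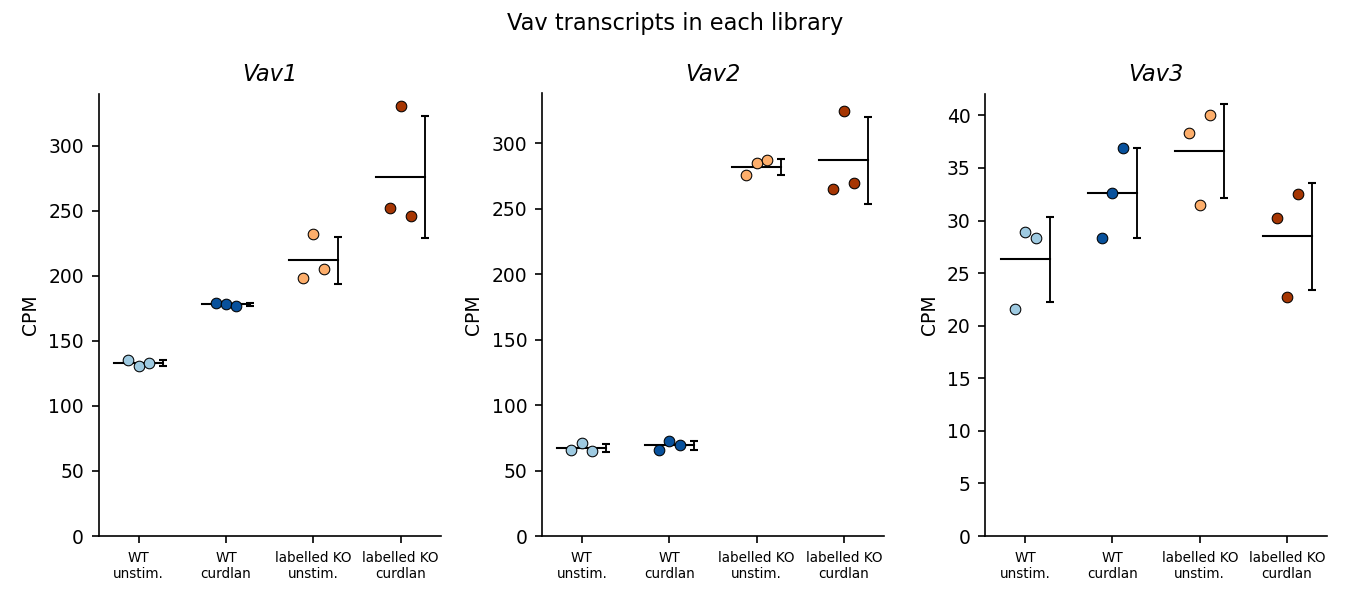
CPM of Vav1, Vav2 and Vav3 (vertical axes, linear from 0) in each of the 12 libraries by group, with a line at the group mean and a bar of 1 SD either side. Vav2 lies between 265 and 325 CPM in every library labelled KO and between 65 and 72.7 CPM in every library labelled WT.

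In WT cells, curdlan induced colony-stimulating factors, cytokines and chemokines. Csf2, which encodes GM-CSF, went from 4 counts over the unstimulated libraries to 1772 counts, a ratio of 549 (95% counting interval 214 to 2020). Tnf rose from 158 ± 20 to 3000 ± 490 CPM (SD, n = 3), a log2 fold change of 4.24 (SE 0.19). Il12b, a subunit shared by IL-12 and IL-23, rose from 12.2 ± 1.3 to 303 ± 100 CPM, and Ptgs2, the inducible cyclooxygenase, from 63.2 ± 8 to 747 ± 59 CPM. Edn1, which encodes the peptide endothelin-1, rose from 3.27 ± 0.64 to 183 ± 58 CPM and the monocyte chemoattractant Ccl7 from 1.92 ± 0.14 to 94 ± 13 CPM. The adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 3.68e-06 for Csf2, 8.58e-08 for Tnf, 5.5e-07 for Il12b, 2.39e-07 for Ptgs2, 1.45e-07 for Edn1 and 4.46e-09 for Ccl7.

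Other large rises in log2 fold change were Csf3 (5.82), Lif (5.80), Ifnb1 (5.68), the EGF-family ligand Areg (4.81), Rsad2 (4.59) and Atp13a4 (4.47). Ifnb1 counts rose by a ratio of 52.8 (counting interval 34 to 86.9). The largest falls were smaller in size and included Ypel2 (-1.73), Gadd45g (-1.70), Mettl13 (-1.35), Zfp36l2 (-1.27), Cep131 (-1.27) and Arrdc3 (-1.20). Of the 22 genes fixed beforehand for the Dectin-1 response, 20 rose, 1 fell and 1 did not pass. Beside those above, cytokine and chemokine genes among them rose by 4.41 (Il23a), 4.36 (Cxcl1), 3.27 (Cxcl2), 2.20 (Il6), 2.16 (Il1b), 1.85 (Il10) and 1.58 (Il2). The transcription factor genes Egr1, Egr2, Egr3 and Nr4a1 rose by 4.06, 1.13, 4.35 and 4.28, and the NF-kB inhibitor genes Nfkbia and Tnfaip3 by 0.80 and 1.44. Among genes of the receptor pathway, Malt1 rose by 1.07, Syk by 0.54 and Bcl10 by 0.45, and Clec7a itself stood at 0.04. Card9 fell by 0.34 on the log2 scale (adjusted p = 0.0198, edgeR with Benjamini-Hochberg adjustment), a call lost without WT unstimulated 1, WT curdlan 2 or WT curdlan 4 (adjusted p up to 0.0958). Of the targeted genes, Vav1 rose by 0.42 (adjusted p = 0.0127, 0.0501 without WT unstimulated 2 and 0.0547 by library size alone), and Vav2 and Vav3 had values of 0.04 and 0.31 that did not pass. With replicate number as a block, the Vav3 value was 0.32 and passed (adjusted p = 0.00295).

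By gene list, 19 of 26 inflammatory cytokine genes rose and none fell (20 rose adjusted over the list alone), with a median log2 fold change of 2.31. Chemokines followed with 14 of 23 rising (16 adjusted over the list alone), a median of 1.51, and Ccl4 (3.77) and Ccl3 (3.43) among the examples. Of 25 NF-kB subunits and targets, 22 rose (24 adjusted over the list alone), among them Nfkbid (3.49) and Nfkbiz (2.14). Immediate-early and NFAT-linked genes rose in 24 of 27 cases and fell in 1 (25 and 1 adjusted over the list alone), with Rcan1, an NFAT target, at 2.88. Of 17 MAPK phosphatase and feedback genes, 12 rose (12 adjusted over the list alone), led by Dusp2 (3.20), Dusp14 (2.89) and Rgs16 (2.81). Dendritic cell maturation genes rose in 17 of 25 cases and fell in 1 (18 and 1 adjusted over the list alone), with Tnfsf4 at 1.89 and Cd83 at 1.54. Of 25 NADPH oxidase and antioxidant genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone), with Nos2, the inducible nitric oxide synthase, at 2.36 and Irg1, the itaconate-producing enzyme, at 1.74. By camera with Benjamini-Hochberg adjustment, the adjusted p of these 7 lists was 7.5e-19 for cytokines, 3.12e-12 for chemokines, 1.07e-22 for NF-kB, 6.75e-25 for immediate-early genes, 3.12e-12 for MAPK feedback, 2.74e-12 for maturation and 2.26e-05 for NADPH oxidase genes. All 7 also passed with an estimated correlation, at an adjusted p = 0.0264 for cytokines and MAPK feedback and 0.0126 for the others.

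A further 8 lists passed only with the preset correlation. Type I interferon response genes rose in 27 of 33 cases (29 adjusted over the list alone), with Ifit2 and Cmpk2 both at 3.48 (camera adjusted p = 5.38e-20, and adjusted p = 0.177 with an estimated correlation). Of 30 glycolysis and hypoxia genes, 16 rose (19 adjusted over the list alone), with P4ha2 at 1.86, Slc2a1 at 1.35 and Hk2 at 1.24 (camera adjusted p = 9.37e-10, and adjusted p = 0.231 with an estimated correlation). Stress response and amino acid transport genes rose in 11 of 23 cases and fell in 1 (11 and 1 adjusted over the list alone), with Vldlr at 1.28 (camera adjusted p = 0.00429, and adjusted p = 0.177 with an estimated correlation). Of 20 inflammasome genes, 8 rose and 2 fell (9 and 3 adjusted over the list alone), with Nlrp3 at 1.73 (camera adjusted p = 0.0179, and adjusted p = 0.0794 with an estimated correlation). C-type lectin receptor pathway genes rose in 13 of 37 cases and fell in 4 (14 and 4 adjusted over the list alone), with Clec4e at 1.19 (camera adjusted p = 0.0125, and adjusted p = 0.0992 with an estimated correlation). Of 27 integrin and adhesion genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone), with Itgb8 at 2.94 (camera adjusted p = 0.0261, and adjusted p = 0.557 with an estimated correlation). The medians of these last lists, 0.11 and 0.07, turned to -0.02 and -0.06 when libraries were scaled by size alone.

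Cell cycle genes fell in 9 of 36 cases (16 fell and 1 rose adjusted over the list alone), with Birc5 at -0.47 and Plk1 at -0.39. The camera adjusted p was 4.18e-05, and adjusted p = 0.459 with an estimated correlation. Only 2 fell without WT unstimulated 4 or WT curdlan 4, and 4 without WT unstimulated 2 or WT curdlan 1. Of 32 ribosomal protein genes, 2 fell (1 adjusted over the list alone), and the list's median was -0.16 (camera adjusted p = 4.35e-06, and adjusted p = 0.459 with an estimated correlation). Sterol synthesis and LXR target genes, 8 of 24 rising and 1 falling (11 and 3 adjusted over the list alone), did not pass (camera adjusted p = 0.0523), but passed with the replicate block (adjusted p = 0.0149). With an estimated correlation and no block its adjusted p was 0.841. Neutrophil markers, 1 of 23 falling, had a median of -0.22 and passed only with that block (camera adjusted p = 0.0559 and, blocked, 5.64e-06, against 0.886 with an estimated correlation and no block). No other marker list passed. Macrophage markers rose in 3 of 24 cases, conventional dendritic cell markers in 7 of 24, and B cell markers in none of 11.

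In all, 3759 genes passed, 2164 higher and 1595 lower with curdlan (57.6% higher), and 671 of them changed at least 2-fold (557 higher, 114 lower). The replicate block raised the count to 7276, and omitting WT curdlan 4 left 2187. The share of higher calls fell to 46.3% with upper-quartile scaling and to 25.1% with scaling by library size alone, under which the median over all genes was -0.167.

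In the libraries labelled KO, curdlan induced cytokine and immediate-early genes, several of them from a higher unstimulated level than in WT. Tnf rose from 942 ± 120 to 4000 ± 870 CPM (SD, n = 3), Il12b from 189 ± 31 to 454 ± 130 CPM and Ptgs2 from 624 ± 100 to 1180 ± 290 CPM. Egr1, an immediate-early transcription factor gene, rose from 19.3 ± 5.5 to 473 ± 50 CPM, and Edn1 from 3.75 ± 0.84 to 237 ± 54 CPM. Il10, an anti-inflammatory cytokine gene, rose from 0.185 ± 0.13 to 4.78 ± 2.6 CPM. The adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 1.05e-05 for Tnf, 0.00182 for Il12b, 0.00195 for Ptgs2, 1.12e-07 for Egr1, 1.66e-07 for Edn1 and 2.64e-05 for Il10.

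Csf2 went from 11 to 1149 counts, a ratio of 129 (counting interval 71.6 to 258), with a log2 fold change of 6.98. The next largest rises were Edn1 (5.97), Areg (5.07), Il10 (4.63), Egr1 (4.61), Nr4a1 (4.50), Ifnb1 (4.39), Egr3 (4.36), Rcan1 (4.06), the EGF-family ligand Hbegf (4.02) and tissue factor, F3 (3.77). The largest falls were Ypel2 (-1.80), Arrdc3 (-1.73), Cbx2 (-1.66), Sephs2 (-1.56) and Narf (-1.56). Of the 22 fixed genes 20 rose and 2 did not pass. Il23a, Tnf, Cxcl2, Cxcl1, Il1b, Il2, Il6, Il12b and Ptgs2 rose by 2.87, 2.09, 2.25, 1.72, 1.67, 1.57, 1.38, 1.27 and 0.92. Egr2 rose by 1.35, Tnfaip3 by 0.76, Clec7a and Bcl10 each by 0.66, Malt1 by 0.53 and Nfkbia by 0.36. Syk and Card9 stood at -0.03 and -0.11 and did not pass. The Cxcl1 call was lost without KO curdlan 5 (1.04, adjusted p = 0.0605) and in a fit of the 2 groups alone (adjusted p = 0.0682), and the Nfkbia call with scaling by library size alone (0.16, adjusted p = 0.192), in edgeR with Benjamini-Hochberg adjustment. Vav1 rose by 0.38 (adjusted p = 0.016, up to 0.0714 without KO unstimulated 1 or 5, and 0.23 in log2 fold change without KO curdlan 4), and Vav1 too lost its call by library size alone (adjusted p = 0.199) and in a fit of the 2 groups alone (adjusted p = 0.0924). Vav2 and Vav3 did not pass, at 0.02 and -0.36.

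Among the lists, only immediate-early and NFAT-linked genes passed by camera with either correlation. They rose in 24 of 27 cases (24 adjusted over the list alone), with a median of 1.20 (camera with Benjamini-Hochberg adjustment, adjusted p = 1.72e-22, and adjusted p = 0.0338 with an estimated correlation). Inflammatory cytokines rose in 23 of 26 cases (23 adjusted over the list alone), with a median of 1.73 and Csf3 at 3.60 (adjusted p = 3.43e-16, and adjusted p = 0.0692 with an estimated correlation). Chemokines rose in 14 of 23 cases (16 adjusted over the list alone), with Ccl7 at 3.28 and Ccl4 at 2.90 (adjusted p = 3.54e-10, and adjusted p = 0.0529 with an estimated correlation). MAPK feedback genes rose in 14 of 17 cases (15 adjusted over the list alone), with Rgs16 at 3.64 (adjusted p = 6.08e-12, and adjusted p = 0.0587 with an estimated correlation). Type I interferon response genes rose in 31 of 33 cases (31 rose and 1 fell adjusted over the list alone), with Cmpk2 at 2.67 and Mx2 at 2.62 (adjusted p = 5.39e-18, and adjusted p = 0.218 with an estimated correlation). NF-kB subunits and targets rose in 16 of 25 cases and fell in 2 (16 and 2 adjusted over the list alone), with a median of 0.38 (adjusted p = 1.3e-05, and adjusted p = 0.218 with an estimated correlation). Maturation genes rose in 14 of 25 cases and fell in 2 (16 and 2 adjusted over the list alone), with Cd80 at 1.39 (adjusted p = 3.48e-05, and adjusted p = 0.104 with an estimated correlation).

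Cell cycle genes fell in 19 of 36 cases and rose in 1 (20 and 1 adjusted over the list alone), with Bub1b, a spindle checkpoint gene, at -0.78 (camera adjusted p = 1.92e-05, and adjusted p = 0.556 with an estimated correlation). Conventional dendritic cell markers rose in 8 of 24 cases and fell in 1 (9 and 1 adjusted over the list alone), with Cd86 at 1.20 (camera adjusted p = 0.00273, and adjusted p = 0.13 with an estimated correlation). NADPH oxidase and antioxidant genes rose in 8 of 25 cases and fell in 1 (8 and 1 adjusted over the list alone), led by Osgin1, which fell by 1.31, and Srxn1 at 1.02 (camera adjusted p = 0.0258, and adjusted p = 0.104 with an estimated correlation). Ribosomal proteins rose in 3 of 32 cases (0 adjusted over the list alone) and in 12 without KO curdlan 2 (camera adjusted p = 0.0125, and adjusted p = 0.903 with an estimated correlation). Scaling by library size alone turned the median of the NADPH oxidase list from 0.12 to -0.08 and that of the ribosomal list from 0.09 to -0.11. Glycolysis and hypoxia genes, 4 rising and 1 falling of 30 (4 adjusted over the list alone), did not pass at a median of -0.01 (camera adjusted p = 0.977).

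In all, 5425 genes passed, 2658 higher and 2767 lower (49.0% higher), and 855 changed at least 2-fold (605 higher, 250 lower). Omitting KO unstimulated 1 left 3488, the block by sample title gave 7861, and with scaling by library size alone 17.9% of calls were higher and the median over all genes was -0.199.

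Set against WT, the fold induction of Il12b, Ptgs2, Ccl7 and Tnf was smaller in the libraries labelled KO, while that of Il10 was larger. The difference of the log2 fold changes, KO minus WT, was -3.37 for Il12b (SE 0.34), -2.64 for Ptgs2 (SE 0.24), -2.33 for Ccl7 (SE 0.2) and -2.16 for Tnf (SE 0.24), n = 3 libraries in each of the 4 groups. For Il10 it was 2.78 (SE 0.58). Gdf15, a stress-induced TGF-beta family cytokine, and Adm, which encodes adrenomedullin, had differences of -2.03 each. Positive differences included Cd72, a lectin-like inhibitory coreceptor (2.18), and the dipeptidase gene Dpep3 (2.46). Cd72 went from 8.26 ± 1.2 to 39.6 ± 4 CPM in the libraries labelled KO and from 9.93 ± 1.3 to 10.5 ± 1.2 CPM in WT. The adjusted p of the edgeR quasi-likelihood interaction test with Benjamini-Hochberg adjustment was 0.00105 for Il12b, 0.000608 for Ptgs2, Ccl7, Gdf15 and Cd72, 0.00195 for Tnf, 0.0046 for Adm and 0.0204 for Il10.

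Unstimulated levels differed between the genotypes for these genes. Tnf, Il12b and Ptgs2 lay at 158, 12.2 and 63.2 CPM in unstimulated WT and at 942, 189 and 624 CPM in unstimulated libraries labelled KO. After curdlan they lay at 3000, 303 and 747 CPM in WT and at 4000, 454 and 1180 CPM in the libraries labelled KO. Ccl7 likewise lay higher there in both states, and despite its smaller fold its gain in CPM was larger there than in WT. Of 684 genes with a negative difference, 373 had risen with curdlan in WT. Of the 684, 107 were higher in the libraries labelled KO with curdlan, 378 were higher there without curdlan, where independent lists would share 144.4, and 411 were lower there with curdlan, where independent lists would share 183.1. A difference of responses uses the same 6 unstimulated libraries as a difference without curdlan and the same 6 curdlan libraries as a difference with it. The correlation across genes was -0.26 without curdlan, where unchanged simulated groups gave -0.69, with covariances of -0.104 and -0.043. With curdlan it was 0.22 against a simulated 0.72, with covariances of 0.086 and 0.046. Part of either excess overlap may therefore come from the shared libraries.

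**Figure D3:**
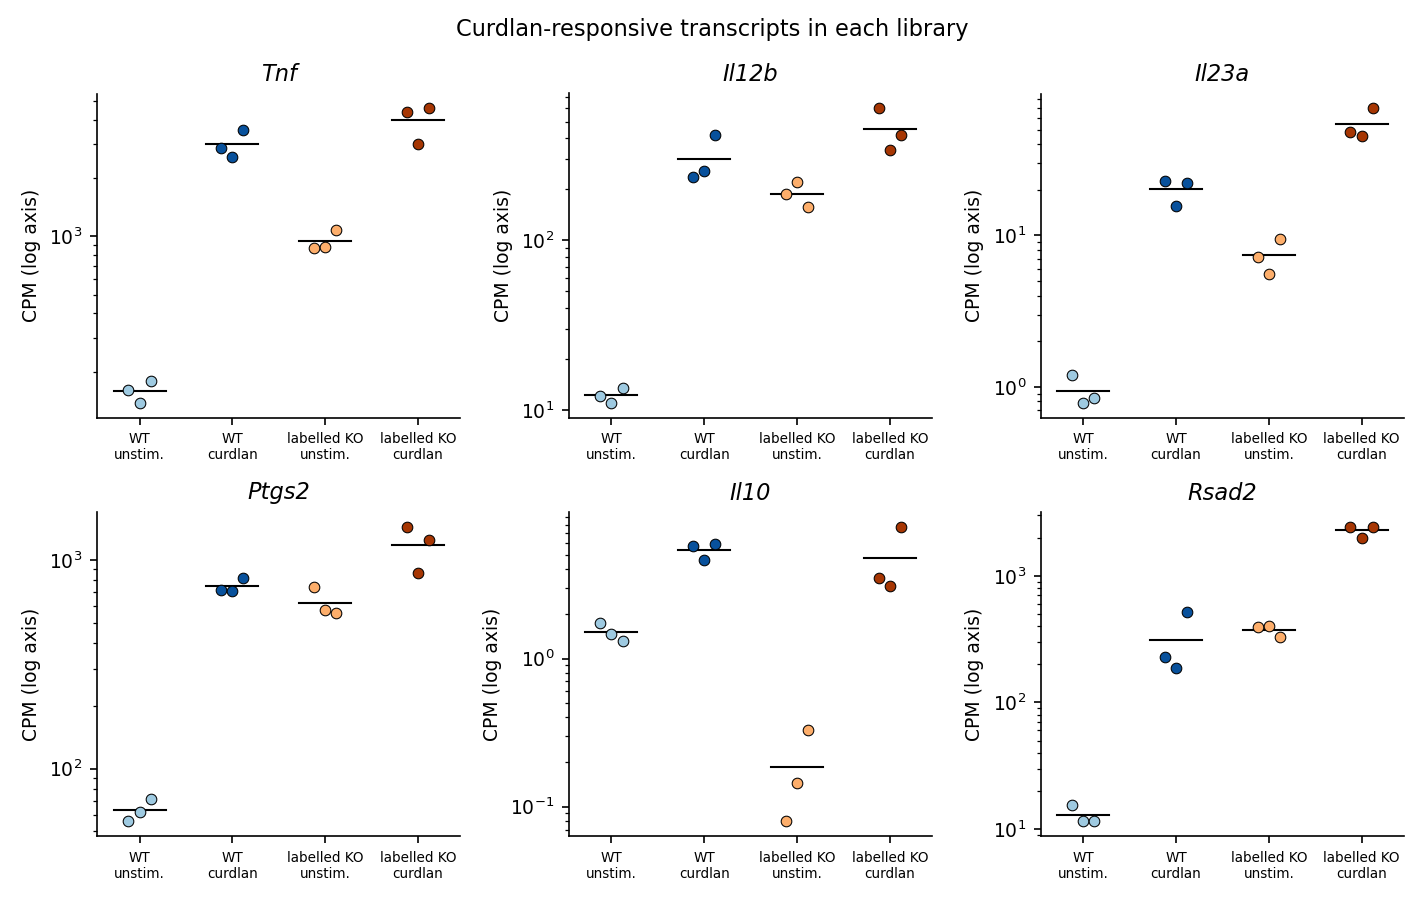
CPM (vertical axes, log scale) of Tnf, Il12b, Il23a, Ptgs2, Il10 and Rsad2 in each of the 12 libraries by group, with a line at each group mean. Unstimulated libraries labelled KO lie above unstimulated WT for 5 of the genes and below it for Il10, which went from 1.5 ± 0.21 to 5.43 ± 0.72 CPM with curdlan in WT.

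Of the 22 fixed genes, 2 had a positive difference, 8 a negative one and 12 did not pass. Beside those given, Il23a (-1.54), Cxcl1 (-2.64), Tnfaip3 (-0.68), Syk (-0.57) and Malt1 (-0.54) were negative and Clec7a (0.63) positive. The values that did not pass were -0.82 for Il6, -0.49 for Il1b, -0.01 for Il2, -1.95 for Csf2, -1.03 for Cxcl2, 0.55 for Egr1, 0.23 for Egr2, 0.01 for Egr3, 0.21 for Nr4a1, -0.45 for Nfkbia, 0.23 for Card9 and 0.21 for Bcl10. With the replicate block, Cxcl2 (-0.86), Il6 (-0.71), Nfkbia (-0.47) and Egr1 (0.73) passed as well, at edgeR adjusted p of 0.000516, 0.00189, 0.00273 and 0.0246 with Benjamini-Hochberg adjustment. Vav1, Vav2 and Vav3 had differences of -0.04, -0.02 and -0.67 and did not pass, and Vav3 passed with the block (-0.50, adjusted p = 0.0101).

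Tnf, Il12b, Ptgs2, Tnfaip3, Syk, Ccl7, Gdf15, Adm and Cd72 kept their calls without any single library. Malt1 lost its call without any library but KO curdlan 2 (edgeR with Benjamini-Hochberg adjustment, adjusted p up to 0.117). Clec7a lost it without any WT library, KO unstimulated 1 or 5 or KO curdlan 5 (up to 0.118), and by library size alone (adjusted p = 0.0618). Cxcl1 lost it without any WT library or KO unstimulated 1 or 5 (up to 0.111), and with robust estimation (adjusted p = 0.0625). Il23a lost it without WT unstimulated 2 or 4, WT curdlan 4, KO unstimulated 1 or KO curdlan 4 (up to 0.066). Il10 lost it without WT unstimulated 1, WT curdlan 2 or KO unstimulated 1 (up to 0.071).

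Other positive differences included Tnc (1.71), Amigo3 (1.55), Ppm1j (1.41), the VEGF receptor gene Flt1 (1.37), Gadd45g (1.36, a gene that fell in WT), Plekhf1 (1.32) and the mitochondrial iron transporter Slc25a28 (1.28). Other negative ones included Lif (-3.32, edgeR adjusted p = 0.0166 with Benjamini-Hochberg adjustment). NF-kB subunits and targets had negative differences in 11 of 25 cases and a positive one in none (19 negative adjusted over the list alone), with a median difference of -0.50 and Nfkbiz (-1.12), Tnip1 (-1.05) and Cflar (-0.92) as examples (camera with Benjamini-Hochberg adjustment, adjusted p = 4.36e-12, and adjusted p = 0.32 with an estimated correlation). Glycolysis and hypoxia genes had negative differences in 10 of 30 cases (13 adjusted over the list alone), with Ero1l (-1.32), Hk2 (-1.24) and Egln3 (-1.20), at a camera adjusted p = 8.31e-09, and adjusted p = 0.46 with an estimated correlation. Only 5 of them passed without WT unstimulated 1, WT unstimulated 2 or KO unstimulated 1. Stress response and amino acid transport genes had negative differences in 9 of 23 cases (11 adjusted over the list alone), with Vldlr (-1.67) and Slc7a2 (-1.09), and in 4 without WT unstimulated 1 (camera adjusted p = 0.00163, and adjusted p = 0.351 with an estimated correlation). Maturation genes had negative differences in 3 of 25 cases (5 negative and 1 positive adjusted over the list alone), namely Icosl (-0.95), Socs3 (-0.95) and Cd83 (-0.89), and in 5 without KO curdlan 2 (camera adjusted p = 0.0363, and adjusted p = 0.46 with an estimated correlation). Ribosomal proteins, with medians of -0.16 in WT and 0.09 in KO, had a positive difference in 1 of 32 cases (19 adjusted over the list alone) and in 15 without KO curdlan 2, at a median of 0.26 (camera adjusted p = 4.12e-11, and adjusted p = 0.46 with an estimated correlation).

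Immediate-early genes, with a median difference of 0.04, had 2 positive and 2 negative differences of 27 (5 past adjusted over the list alone), and the list did not pass (camera adjusted p = 0.725). Type I interferon response genes, at a median of -0.10, did not pass (1 positive, 4 negative, and 5 past adjusted over the list alone, camera adjusted p = 0.473). Inflammatory cytokines had 7 negative and 2 positive differences of 26 (8 and 2 adjusted over the list alone) and chemokines 3 negative ones of 23 (4 adjusted over the list alone), both at a camera adjusted p = 0.0529. With the replicate block these lists passed (adjusted p = 0.000823 and 0.0134), as did NADPH oxidase genes (0.00104), sterol genes (1.32e-05) and conventional dendritic cell markers (0.0134). With an estimated correlation and no block, the camera adjusted p of these 5 lists was 0.851, 0.627, 0.351, 0.946 and 0.851. Without the block no marker list passed.

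In all, 989 genes had responses that differed, 305 with a positive and 684 with a negative difference (30.8% positive). The sign does not give the size of a response, since a gene that falls with curdlan has a positive difference where it falls less in KO. The count was 2671 with the replicate block, 4485 with the block by sample title (2018 positive, 2467 negative) and 2252 with DESeq2, and without single libraries it ran from 385 (WT unstimulated 1) to 2859 (KO curdlan 2). It also moved to 504 and 598 without WT unstimulated 2 and 4, to 387 and 593 without WT curdlan 2 and 4, to 397 and 637 without KO unstimulated 1 and 5, and to 616 without KO curdlan 4. Positive differences made up 48.6% of calls without KO curdlan 2, 46.9% with voom, 39.6% with the replicate block, 42.0% with upper-quartile scaling, 42.2% with DESeq2 and 15.7% with scaling by library size alone.

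**Figure D4:**
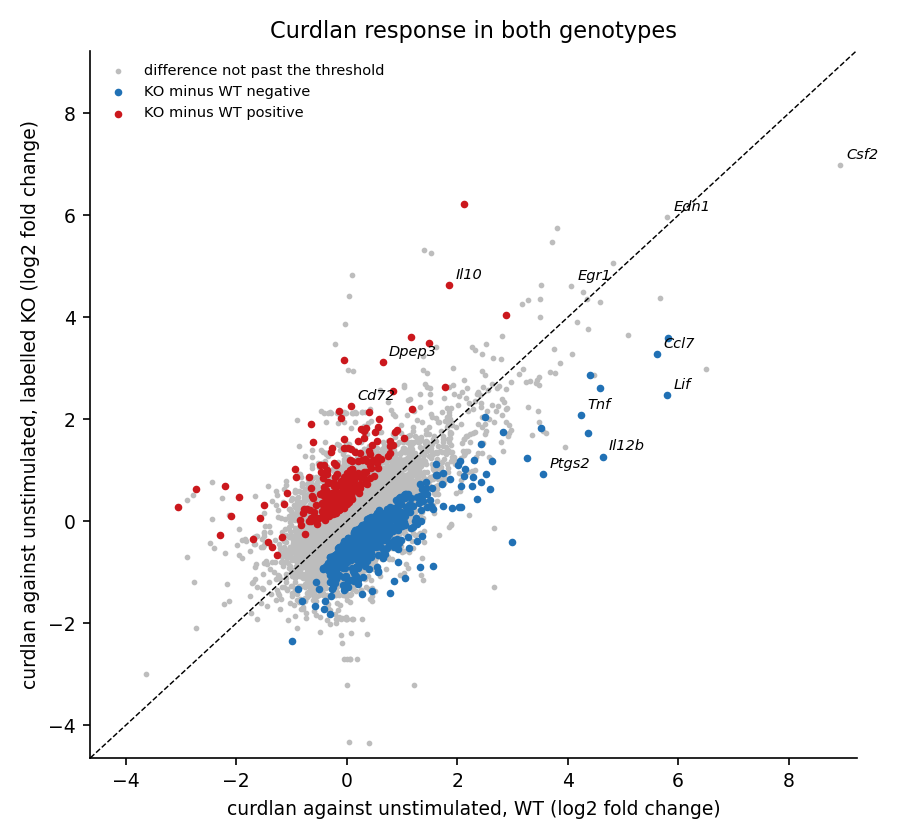
Log2 fold change with curdlan in WT (horizontal axis) and in the libraries labelled KO (vertical axis) for the 18981 tested genes, with genes past the threshold in blue where KO minus WT was negative and in red where it was positive, and a dashed line of equal responses. By construction the 684 blue genes lie below the line and the 305 red genes above it.

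Across the 671 genes that curdlan changed at least 2-fold in WT, the summed change in the libraries labelled KO was 69.6% of that in WT, and 625 moved in the same direction. Genes chosen in one group regress toward 0 in the other by chance. Across the 855 genes chosen in the libraries labelled KO, the WT change was 69.8% of the KO change. Called in both genotypes were 2106 genes, of which 1152 rose in both, 845 fell in both and 109 went opposite ways. Independent lists would share 303 rising and 232.5 falling genes. The log2 fold changes correlated across genes at 0.57, and genes are not independent replicates.

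Without curdlan, libraries labelled KO already expressed interferon-stimulated, inflammatory and macrophage-associated genes at higher levels, and several immunoglobulin transcripts were far lower there. Rsad2, an interferon-induced antiviral gene, lay at 12.8 ± 2.3 CPM in WT and 374 ± 40 CPM in the libraries labelled KO (SD, n = 3). Apoe, the lipid carrier apolipoprotein E, lay at 13.8 ± 3.2 and 1640 ± 240 CPM, the complement component C1qa at 62.1 ± 22 and 1190 ± 83 CPM, and Ccl7 at 1.92 ± 0.14 and 81.1 ± 11 CPM. Ighm, the immunoglobulin mu heavy chain, lay at 698 ± 120 CPM in WT and 19.4 ± 3.1 CPM in the libraries labelled KO. Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 5.1e-07 for Rsad2, 2.13e-10 for Apoe, 2.6e-07 for C1qa and 6.55e-10 for Ccl7.

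Beside Apoe, with a log2 fold change of 6.89 (SE 0.19), the largest excesses in unstimulated libraries labelled KO were Cd209e (6.68), Ogdhl (6.48), Cd209d (6.04), Ccl7 (5.40), Ccl12 (5.34), the TAM receptor ligand Gas6 (5.15), Rsad2 (4.86) and the sodium channel gene Scn3a (4.68). Ighg1 had no count in the libraries labelled KO and was at least 3570-fold lower, taking 3 counts over the group as the floor. By the same measure Ighg3 was at least 3050-fold, the plasma cell gene Mzb1 at least 1010-fold, Ighv3-6 at least 670-fold, Iglv1 at least 551-fold and the B cell gene Ms4a1 at least 513-fold lower. Jchain, the joining chain of secreted antibody, fell from 14543 counts in WT to 7, a ratio of 1620 (counting interval 785 to 4030). Intervals and floors here cover counting error only. Immunoglobulin, Cd209 and Ifit genes share sequence within their families, and how reads with several matches were counted is not given in the sources used here, so single members are uncertain.

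Of the 22 fixed genes 13 were higher, 2 lower and 7 did not pass. Higher were Il12b (3.95), Ptgs2 (3.30), Il23a (2.96), Cxcl1 (2.74), Tnf (2.57), Cxcl2 (2.20), Il6 (1.79), Tnfaip3 (1.22), Nfkbia (1.03), Malt1 (0.98), Il1b (0.86), Syk (0.65) and Bcl10 (0.56). Il10 was lower by -2.97 and Clec7a by -0.34. The others had values of 1.71 (Csf2), 0.15 (Egr1), 0.13 (Egr2), 0.39 (Egr3), 0.43 (Nr4a1), 0.13 (Il2) and -0.21 (Card9). The Clec7a call was lost without WT unstimulated 1 or 2 or KO unstimulated 1 or 5 (edgeR with Benjamini-Hochberg adjustment, adjusted p up to 0.101). That of Il1b was lost without any unstimulated WT library, WT curdlan 2, KO unstimulated 1 or KO unstimulated 5, the last of which gave 0.46 (adjusted p = 0.216), by library size alone (adjusted p = 0.0825), with robust estimation (adjusted p = 0.0594) and in DESeq2 (adjusted p = 0.0509).

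All 33 type I interferon response genes were higher (33 adjusted over the list alone), with a median of 2.30 and Ifit2 at 4.63, Ifit1 at 4.56 and Oasl1 at 4.17. The camera adjusted p was 1.01e-19, and adjusted p = 0.193 with an estimated correlation. Of 25 NF-kB subunits and targets, 23 were higher (24 adjusted over the list alone), with Nfkbiz at 2.05 and Icam1 at 1.99 (adjusted p = 2.35e-15, and adjusted p = 0.0849 with an estimated correlation). Chemokines were higher in 17 of 23 cases and lower in 2 (17 and 2 adjusted over the list alone), with a median of 2.02 and Cxcl5 at 3.84 (adjusted p = 7.34e-07, and adjusted p = 0.0849 with an estimated correlation). Inflammatory cytokines were higher in 18 of 26 cases and lower in 2 (20 past adjusted over the list alone), among them Il27 at 2.99 (adjusted p = 1.98e-05, and adjusted p = 0.232 with an estimated correlation). Immediate-early genes were higher in 14 of 27 cases and lower in 3 (16 and 3 adjusted over the list alone), at a median of 0.47 (adjusted p = 0.000416, and adjusted p = 0.232 with an estimated correlation). Antigen presentation genes were higher in 16 of 23 cases and lower in 2 (17 and 2 adjusted over the list alone), with the MHC class II transactivator Ciita at 1.85 and H2-Eb1 at 1.53 (adjusted p = 1.81e-05, and adjusted p = 0.193 with an estimated correlation). Cell cycle genes were lower in 35 of 36 cases (35 adjusted over the list alone), with a median of -0.97 and Bub1b at -1.39 (adjusted p = 1.01e-17, and adjusted p = 0.113 with an estimated correlation).

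Smaller shifts toward the libraries labelled KO were called for 7 further lists. These were the C-type lectin receptor pathway with 17 of 37 higher and 5 lower (17 and 6 adjusted over the list alone), NADPH oxidase genes with 11 of 25 and 3, and inflammasome genes with 10 of 20 and 2. Lysosome and phagosome genes had 13 of 30 higher and 2 lower, glycolysis and hypoxia genes 12 of 30 and 4, eicosanoid synthesis genes 10 of 20 and 2, and integrins and adhesion genes 12 of 27 and 5. Adjusted over the list alone the last 6 lists had 15, 13, 16, 19, 13 and 18 past. Their camera adjusted p lay between 0.00245 for NADPH oxidase genes and 0.0167 for integrins, and with an estimated correlation adjusted p = 0.0849 for the lectin pathway, NADPH oxidase and inflammasome lists, 0.491 for lysosome and integrins, 0.647 for glycolysis and 0.211 for eicosanoids. Examples were Clec4e at 1.60, Nos2 at 1.96, the pyrin gene Mefv at 3.75, Sqstm1 at 1.75, Vegfa at 1.51, prostacyclin synthase, Ptgis, at 3.40, and Thbs1 at 1.67. Scaling by library size alone turned the median of the lectin pathway list from 0.11 to -0.07 and that of the integrins from 0.18 to 0.00. The inflammasome list had 6 higher without KO unstimulated 1. Sterol genes, 5 higher and 10 lower of 24 (6 and 11 adjusted over the list alone), had a median of -0.28 and a mean of 0.08 and did not pass (camera adjusted p = 0.253).

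Markers of other cell types moved with the genotype label. B cell markers were lower in 10 of 11 cases (10 adjusted over the list alone), with a median of -4.54 (camera adjusted p = 2.83e-08, and adjusted p = 0.0849 with an estimated correlation). Macrophage markers were higher in 19 of 24 cases and lower in 2 (20 and 2 adjusted over the list alone), with a median of 0.90 and C1qc at 3.69 (adjusted p = 4.72e-08, and adjusted p = 0.142 with an estimated correlation). Neutrophil markers were higher in 20 of 23 cases (20 adjusted over the list alone), with Retnlg at 1.81 and Mpo at 1.63 (adjusted p = 4.79e-07, and adjusted p = 0.422 with an estimated correlation). Mast cell and basophil markers were higher in 11 of 15 cases and lower in 1 (12 past adjusted over the list alone), with Tpsb2 at 4.24 (a ratio of 19.8 in counts, interval 11.7 to 35.9) and Hdc at 2.81 (adjusted p = 5.92e-06, and adjusted p = 0.212 with an estimated correlation). Conventional dendritic cell markers went both ways, 11 higher and 7 lower of 24 (20 past adjusted over the list alone), with a median of 0.05 and a mean of -0.06. Clec9a, a receptor of cross-presenting dendritic cells, fell from 9.33 ± 1.5 to 0.176 ± 0.11 CPM and Cd209a was higher by 4.10. That list did not pass (camera adjusted p = 0.421).

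The remaining lists reported here did not pass in any comparison. Without curdlan, plasmacytoid dendritic cell markers had 5 higher and 4 lower of 11 (10 past adjusted over the list alone), with a median of 0.30, a mean of -0.51 and a camera adjusted p = 0.979. Eosinophil markers had 2 higher and 4 lower of 10 (6 past adjusted over the list alone), with a median of 0.11, a mean of -0.23 and a camera adjusted p = 0.53. T cell markers had 2 higher and 5 lower of 11 (7 past adjusted over the list alone, camera adjusted p = 0.467), and NK cell markers 1 of each of 6 (2 past adjusted over the list alone), with a median of -0.10, a mean of 0.13 and a camera adjusted p = 0.912. Erythroid and megakaryocyte markers had 4 higher and 1 lower of 10 (5 past adjusted over the list alone, camera adjusted p = 0.134), and stromal and osteoclast markers 6 and 4 of 14 (10 past adjusted over the list alone, camera adjusted p = 0.587). None of 3 sex-linked genes passed (0 adjusted over the list alone, camera adjusted p = 0.828), with Xist at 783 ± 11 and 843 ± 57 CPM in WT and in the libraries labelled KO.

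In all, 8428 genes passed without curdlan, 4007 higher and 4421 lower in the libraries labelled KO (47.5% higher), and 2387 differed at least 2-fold (1231 higher, 1156 lower). With scaling by library size alone 26.4% were higher and the median over all genes was -0.191.

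With curdlan, Apoe, C1qa, Rsad2 and Ccl7 were higher in the libraries labelled KO, while Tnf did not pass. Apoe lay at 13.8 ± 1.5 CPM in WT and 1460 ± 63 CPM in the libraries labelled KO (SD, n = 3), C1qa at 59.8 ± 21 and 1180 ± 100 CPM, and Rsad2 at 309 ± 180 and 2280 ± 260 CPM. Ccl7 lay at 94 ± 13 and 789 ± 130 CPM. Tnf, at 3000 ± 490 and 4000 ± 870 CPM, differed by 0.42 and did not pass (edgeR quasi-likelihood with Benjamini-Hochberg adjustment, adjusted p = 0.0561, against 3.1e-10 for Apoe). Il10, at 5.43 ± 0.72 and 4.78 ± 2.6 CPM, differed by -0.19 and did not pass either (adjusted p = 0.631).

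After Cd209e (7.43), Ogdhl (7.23) and Apoe (6.73), the largest excesses were Cd209d (6.59), Gas6 (5.11), Cd209a (5.01), Ccl12 (4.96), Scn3a (4.35) and C1qa (4.30). In counts, Cd209e had a ratio of 187 (interval 109 to 351) and Ogdhl of 155 (93.6 to 277). Ighg1 was at least 2860-fold, Mzb1 at least 757-fold, Ighv3-6 at least 508-fold and Iglv1 at least 460-fold lower, with no count in the libraries labelled KO and the floor as above. Ighg3, with 1 count there, had a ratio of 7240 (counting interval 1300 to 286000). Jchain, at 7 counts, had a ratio of 1250 (608 to 3120). The sialyltransferase gene St6galnac2, at 4 counts, had a ratio of 944 (369 to 3470). Its log2 fold change was -9.78, with Igkc at -9.37 and BC018473 at -9.03. BC018473 is annotated as antisense, and the library kit does not keep strand, so that its value is uncertain.

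Of the 22 fixed genes 12 were higher and 10 did not pass. Higher were Il23a (1.42), Cxcl2 (1.17), Il6 (0.98), Bcl10 (0.77), Egr1 (0.70), Ptgs2 (0.66), Nr4a1 (0.65), Il12b (0.58), Nfkbia (0.58), Tnfaip3 (0.54), Malt1 (0.44) and Egr2 (0.36). Not past the threshold, beside Tnf and Il10, were Il1b (0.37), Il2 (0.12), Csf2 (-0.23), Cxcl1 (0.11), Egr3 (0.41), Clec7a (0.28), Syk (0.09) and Card9 (0.02). Il12b (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.0498) lost its call without any unstimulated WT library, WT curdlan 1 or 2, KO unstimulated 1 or 2, or KO curdlan 2 or 5. It lay at 0.33 without KO curdlan 2 (adjusted p = 0.23) and at 0.88 without WT curdlan 4 (adjusted p = 0.00546). Robust estimation (adjusted p = 0.0659) and a fit of the 2 groups alone (adjusted p = 0.108) ended the Il12b call too. Il6 lost its call without WT curdlan 1 or 2 or KO curdlan 5, the last of which gave 0.53 (adjusted p = 0.0921). With scaling by library size alone the calls of Il12b (adjusted p = 0.231), Il6 (0.0537), Egr2 (0.297), Malt1 (0.0972) and Nr4a1 (0.0707) were lost.

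The interferon list was higher in all 33 cases (33 adjusted over the list alone), with a median of 1.90 and Ifit3 at 3.44 (camera with Benjamini-Hochberg adjustment, adjusted p = 1.34e-18, and adjusted p = 0.206 with an estimated correlation). Chemokines were higher in 18 of 23 cases and lower in 2 (20 past adjusted over the list alone), and NF-kB genes higher in 19 of 25 (21 adjusted over the list alone), at adjusted p of 1.1e-05 and 3.15e-06, and adjusted p = 0.206 for both with an estimated correlation. Inflammatory cytokines, 14 higher and 3 lower of 26 (15 and 3 adjusted over the list alone), had a median of 0.62 (adjusted p = 0.0138, and adjusted p = 0.553 with an estimated correlation). Immediate-early genes were higher in 20 of 27 cases and lower in 2 (22 past adjusted over the list alone), with Rcan1 at 1.33 (adjusted p = 4.15e-05, and adjusted p = 0.206 with an estimated correlation). Antigen presentation genes were higher in 16 of 23 cases and lower in 1 (16 and 2 adjusted over the list alone), with H2-Aa at 1.61 (adjusted p = 6.02e-06, and adjusted p = 0.206 with an estimated correlation). Ribosomal proteins were higher in 25 of 32 cases (25 adjusted over the list alone), with Rplp2 at 0.79 (adjusted p = 3.15e-06, and adjusted p = 0.494 with an estimated correlation). Cell cycle genes were lower in 33 of 36 cases (34 adjusted over the list alone), with Bub1b at -1.79 and Ccnb1 at -1.62 (adjusted p = 2.11e-16, and adjusted p = 0.206 with an estimated correlation). Sterol genes were lower in 15 of 24 cases and higher in 2 (17 past adjusted over the list alone), with Nsdhl at -1.18 and Lss at -1.17 (adjusted p = 0.0265, and adjusted p = 0.678 with an estimated correlation). Lysosome genes, 14 higher and 4 lower of 30 (18 past adjusted over the list alone), had a median of 0.23 that scaling by library size alone turned to -0.02 (adjusted p = 0.00385, and adjusted p = 0.553 with an estimated correlation). Inflammasome genes, 9 higher and 2 lower of 20 (11 past adjusted over the list alone), had a median of 0.28 (adjusted p = 0.0281, and adjusted p = 0.206 with an estimated correlation).

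B cell markers were lower in 10 of 11 cases (10 adjusted over the list alone), at a median of -4.77, and macrophage markers higher in 16 of 24 and lower in 3 (17 and 3 adjusted over the list alone), at a median of 1.04. Neutrophil markers were higher in 18 of 23 cases (20 adjusted over the list alone), with Stfa2 at 2.16, and mast cell and basophil markers in 12 of 15 (14 past adjusted over the list alone), with Mcpt8 at 2.96. Their camera adjusted p with Benjamini-Hochberg adjustment was 2.63e-07, 1.55e-06, 6.02e-06 and 1.1e-05, and with an estimated correlation adjusted p = 0.206, 0.206, 0.552 and 0.247. Xist stood at 0.10 and did not pass (edgeR adjusted p = 0.411).

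In all, 9762 genes passed with curdlan, 4682 higher and 5080 lower in the libraries labelled KO (48.0% higher), and 2553 differed at least 2-fold (1178 higher, 1375 lower). With scaling by library size alone 23.7% were higher and the median over all genes was -0.236. Higher in both states were 2623 genes (988.4 for independent lists) and lower in both 3310 (1183). The 2 states share no library but, by the pairing, may share sources. The differences correlated across genes at 0.92.

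**Figure D5:**
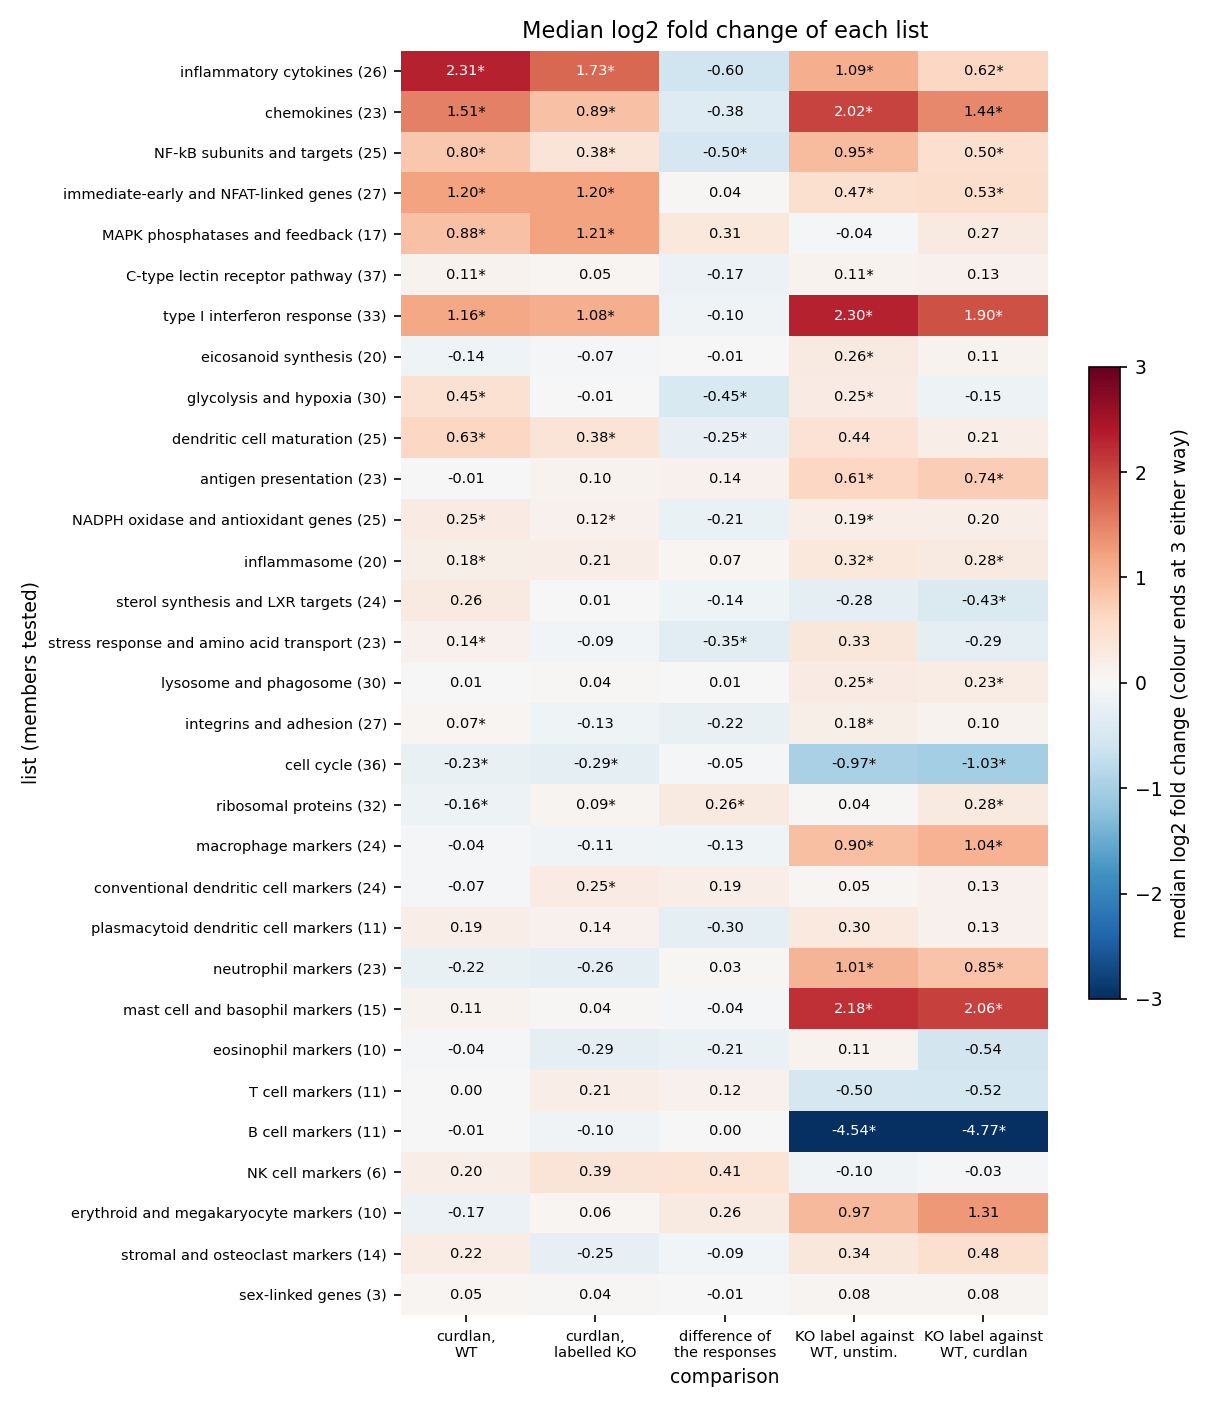
Median log2 fold change (colour, from -3 to 3) of 31 of the 32 gene and marker lists (vertical axis, members tested in brackets) in the 5 comparisons (horizontal axis), with an asterisk where camera with a preset correlation passed. The interferon list is past the threshold in all comparisons but the difference of responses, and the B cell markers in both comparisons of genotypes, and none of these calls passed with an estimated correlation.

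The authors' deposited table of KO against WT with curdlan held 8145 genes past an adjusted p of 0.05, 3778 higher and 4367 lower, and its log2 fold changes correlated at 0.9764 across 11450 genes with those computed here for that comparison. It gave Vav1, Vav2 and Vav3 at 0.62, 2.01 and -0.19. The authors' deposited table named an interaction held 8270 such genes. Its values correlated at 0.9988 with KO against WT without curdlan and at -0.2501 with the difference of responses, and it gave Vav1, Vav2 and Vav3 at 0.69, 2.08 and 0.49. By its values the table holds KO against WT without curdlan. The difference of responses given here rests on the counts alone.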

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

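The tests of exchanged single libraries, mixed cells, targeted alleles, earlier stimulation, scaling, lane, chromosome segments and the share of the main cell type were chosen only after the results they bear on were seen. The reading of the relabellings by their spread was also added afterwards.

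The results singled out here are responses to curdlan that differed between the genotypes by the interaction test. There were 989 such genes. Among the genes fixed beforehand, the differences (KO minus WT, log2) were -3.37 for Il12b, -2.64 for Cxcl1 and Ptgs2, -2.16 for Tnf, -1.54 for Il23a, -0.68 for Tnfaip3, -0.57 for Syk, -0.54 for Malt1, 0.63 for Clec7a and 2.78 for Il10. Positive differences were those of Dpep3 (2.46), Cd72 (2.18), Tnc (1.71), Amigo3 (1.55), Pdzk1ip1 (1.48), Ppm1j (1.41), Flt1 (1.37), Gadd45g (1.36, a smaller fall), Plekhf1 (1.32) and Slc25a28 (1.28). Negative differences were those of Lif (-3.32), Ccl7 (-2.33), Csf3 (-2.23), Gdf15 (-2.03), Adm (-2.03) and Rsad2 (-1.98). List members with differences were Icam1 (-1.13), Nfkbiz (-1.12), Tnip1 (-1.05), Cflar (-0.92), Ero1l (-1.32), Hk2 (-1.24), Egln3 (-1.20), P4ha2 (-1.03), Icosl (-0.95), Socs3 (-0.95), Cd83 (-0.89), Vldlr (-1.67), Ddit4 (-1.31), Slc7a2 (-1.09), Herpud1 (-1.01) and Rpl27a (0.50). By list, median differences were -0.50 for NF-kB genes, -0.45 for glycolysis and hypoxia, -0.35 for the stress response, -0.25 for dendritic cell maturation and 0.26 for ribosomal proteins, and none of these 5 lists passed with an estimated correlation.

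Some of these calls rest on single libraries (edgeR with Benjamini-Hochberg adjustment). Csf3 lost its call without any WT library, KO unstimulated 1 or 5 or KO curdlan 4 (adjusted p up to 0.106), Pdzk1ip1 without any WT library, KO unstimulated 1 or KO curdlan 4 (up to 0.103), and Rpl27a without any library but KO curdlan 2 (up to 0.119). Icam1 lost it without any unstimulated WT library, WT curdlan 2 or 4, KO unstimulated 1 or KO curdlan 4 (up to 0.079), and Herpud1 without any unstimulated WT library or WT curdlan 1 or 2 (up to 0.0819). Rsad2 lost it without WT unstimulated 2 or 4, KO unstimulated 1 or KO curdlan 4 (up to 0.0576), P4ha2 without WT unstimulated 1 or 2 or KO unstimulated 1 (up to 0.0564), and Ddit4 without WT unstimulated 1 or KO unstimulated 1 (up to 0.052).

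Of 100 relabellings of genotype within each state, 4 gave as many interaction calls as the 989 of the real labels, the real one included, and the highest other count was 2764. These counts do not exclude chance. A relabelling that mixes the genotypes moves their difference into the spread, and the median common dispersion of the 99 others was 0.104 against 0.014 for the real labels, so that the relabelling itself lowers the counts, and 87 of them called 0 genes. The 3 that gave more calls than the real labels, 2669, 2764 and 1963, each exchanged 2 of 3 libraries between the genotypes in 1 state only, so that they point to the structure of the samples, a large difference between genotypes that then enters the interaction. For curdlan in WT, 1 of 10 splits of the 6 libraries, the real one with 3759 calls, was as large, and the highest other called 0 genes. In the libraries labelled KO it was 1 of 10 with 5425 calls and a highest other of 301. For KO against WT with and without curdlan it was 1 of 10 with 9762 and 8428 calls and highest others of 0. Splits of 6 libraries are too few for a share under 0.05.

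No Vav transcript passed as lower in libraries labelled KO. An exchange of single libraries between the genotypes is argued against by the lowest Vav2 level under the KO label, 3.64 times the highest under the WT label. Wild-type cells mixed into the KO cultures could at most bring Vav2 to the WT level, and its log2 fold change was 2.07 (SE 0.08). Targeted alleles that leave a transcript without function stay open, since 0 of the deposited columns count exons. An exchange of all libraries of both genotypes would also put Vav2 higher under the KO label in every library, and it stays open, untested, like any wrong label for a whole group.

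Inflammatory and interferon genes were higher in unstimulated libraries labelled KO. If those cells had been stimulated as for 3 hours of curdlan, immediate-early genes would be higher by about their median WT rise of 1.20, and the median over all 27 tested members of the list was 0.47 (SD 0.53). Scaling is argued against by a median of 2.12 for the interferon list with library size as the only scaling, against 2.30. The sequencing lane stays open and cannot be told apart from the genotype, since 0 lanes held more than 1 group. The genotype itself, a stimulus of another kind or length, and the shift in marker genes stay open as well.

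B-lineage transcripts were far lower and macrophage markers higher in the libraries labelled KO. A lower share of the main cell type there, with nothing else changed, would raise the markers of every other type. The macrophage median lay 5.44 above the B cell median, which argues against that shift only as the whole cause. Neutrophil and mast cell markers were higher too, and such a shift beside a separate loss of B-lineage cells stays open. Chromosome segments carried along with the targeted loci are argued against as the whole cause by 0.533% of genes within 10 Mb of the 3 loci differing at least 4-fold in both states, against 2.71% elsewhere. Of the 588 such genes, 3 lay near the loci, 462 elsewhere, 122 had no coordinates and 1 was Vav2, which is left out. B-lineage cells in the WT cultures alone are a candidate explanation that stays open: 9 further B-lineage genes had a median of -0.89, short of the -2 set beforehand as its sign and past the bound of -1 set beforehand against it. By that bound alone the test argues against this explanation. It is kept open because the median lies past the bound by less than the median standard error, a requirement added after that value was seen. Of these genes Cr2 stood at -2.82, Derl3 at -2.50, Fcrl1 at -1.33, Fcer2a at -0.89, Eaf2 at -0.55, Tnfrsf13c at -0.37, Bank1 at 0.10 and Siglecg at 0.56, and Fcrl5 had no count in unstimulated libraries labelled KO, while the most abundant B-lineage transcript of the marker list, Ighm, lay at 698 CPM in WT.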

How the results depend on the processing

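Of the settings in this part, scaling by library size alone and the block by the numbers of the authors' comparison table were chosen after seeing the data. Where a value below changed, the cause was not tested unless stated. Of 666 pairs of named gene and comparison, 626 were past the threshold. None of these turned direction under any setting, and 90 lost the threshold under at least 1, 79 of them without some library and 5 with the replicate block. Over all named pairs and left-out libraries, 7562 values kept their direction and side, 387 lost the threshold, 12 gained it and 31 turned. RLE factors, robust estimation and no filter moved none of the 5 counts of genes by over 1.5 times. Depth limits the genes with few counts, such as Csf2, whose unstimulated level rests on 4 counts.
The block paired the libraries by number. In WT every library correlated best with its own number (6 of 6), and in KO 4 of 4, while across genotypes the numbers gave -0.13, -0.04, 0.08 and -0.15 and are only shared numbers. For KO against WT the block still tied libraries of both genotypes by these numbers, so that calls changed there rest on an arbitrary pairing. It changed calls to 7276 for curdlan in WT and 2671 for the difference of responses, and the interaction lists past the threshold from 5 to 10. Calls lost with the block were those of Ear6, Epx, Pacsin1 and Rplp1 in KO and Nkg7 between genotypes with curdlan, beside the ribosomal list in KO (camera adjusted p = 0.119). Gained, beyond those given with the results, were Clec7a (0.31), Csf2 (-0.62) and Il10 (-0.68) between genotypes with curdlan, and the inflammasome (camera adjusted p = 0.0115) and neutrophil (0.00137) lists in KO, against 0.169 and 0.907 with an estimated correlation and no block. It changed no other call of a named gene, nor of a list in WT, KO and the difference. Lists were not tested with it for KO against WT. Reversed with it were Vav2 in KO (-0.10), Il2 (0.09) in the difference, and Cxcl1 (-0.27) and Il1b (-0.04) between genotypes with curdlan. The block by title gave 6551 calls for WT and 4485 for the difference, with Il2 at 0.01 and Cxcl1 at -0.09. The block by the comparison table gave Vav2 -0.10, Il2 0.12, Cxcl1 -0.34 and Il1b -0.05.
Voom gave 6340 calls for WT and 2195 for the difference, with Il2 at 0.26, Cxcl1 at -0.17 and Csf2 at 0.06 reversed. DESeq2 gave 2252 for the difference, and a fit of only the 2 groups 3098 for KO and 5214 for WT, reversing the order. A minimum change of 1 left, by construction, 671, 855, 203, 2553 and 2387 calls in WT, KO, the difference, and KO against WT with and without curdlan. With an estimated correlation 7, 1, 0, 0 and 0 lists passed camera in the same order, against 15, 11, 5, 15 and 18. Upper-quartile scaling reversed Clec7a in WT (0.00) and, in the difference, Il2 (0.04), Vav1 (0.01) and Vav2 (0.02).
Scaling by library size alone gave 6123 calls for WT. It reversed Clec7a (-0.09) and Vav2 (-0.09) in WT, Vav2 in KO (-0.18), Egr3 in the difference (-0.05), Card9 (-0.22), Il2 (-0.12), Syk (-0.16) and Cxcl1 (-0.14) with curdlan, and Egr1 (-0.04), Egr2 (-0.05) and Il2 (-0.05) without. List medians it reversed were those of the lectin pathway in WT (-0.02) and without curdlan (-0.07), NADPH oxidase (-0.08) and ribosomal genes (-0.11) in KO, lysosome genes with curdlan (-0.02), and integrins in WT (-0.06) and without curdlan (0.00). The shift of all genes by this scaling is in the same direction.
Leaving out 1 library, calls ran from 2187 to 4273 in WT, 3488 to 6091 in KO, 385 to 2859 for the difference, 7991 to 9789 with curdlan and 7087 to 8807 without. The share of the WT response seen in KO, 69.6%, ran from 64.9% to 74.1%. Over genes selected in KO it was 118%, signed by the WT change and divided by the summed size of the WT change, and so not the inverse of the 69.8% signed by the KO change. It was 72.5% over changes of at least 2 in log2, 74.0% for rising and 43.2% for falling genes, and 75.7% with the strict filter. Values not past the threshold that turned without some library ran, in KO, from -0.06 to 0.02 (Syk) and -0.08 to 0.08 (Vav2), and in WT from -0.02 to 0.12 (Clec7a). In the difference they ran from -0.26 to 0.35 (Egr3), -0.33 to 0.40 (Il2), -0.19 to 0.04 (Vav1) and -0.12 to 0.03 (Vav2). Between genotypes with curdlan they ran from -0.05 to 0.08 (Card9), -0.56 to 0.34 (Csf2), -0.58 to 0.51 (Cxcl1), -0.72 to 0.04 (Il10), -0.06 to 0.58 (Il1b) and -0.21 to 0.52 (Il2), and without from -0.04 to 0.35 (Egr1). Those of Vav2 in WT (0.01 to 0.08), Syk with curdlan (0.05 to 0.14), Egr2 (0.09 to 0.16) and Il2 (0.00 to 0.26) without, and of the lists turned by library size kept their sign, namely the lectin pathway (0.08 to 0.14 and 0.06 to 0.18), NADPH oxidase (0.11 to 0.17), lysosome (0.17 to 0.32), ribosomal (0.07 to 0.13) and integrin genes without curdlan (0.12 to 0.24), while integrins in WT turned (-0.04 to 0.16).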

Other observations

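Several neighbouring genes on GRCm38 chromosome 11, chosen after their values were seen, were far lower in the libraries labelled KO. Without curdlan, St6galnac2 (116675303 to 116694868), a sialyltransferase gene, lay at 45.7 CPM in WT and 0.076 CPM in the libraries labelled KO, and St6galnac1 (116765025 to 116775507) at 8.03 and 0.1 CPM. Their log2 fold changes were -9.20 and -6.35 without curdlan, and St6galnac2, at 11 counts, had a ratio of 610 (counting interval 341 to 1220). Cygb, the cytoglobin gene (116645595 to 116654313), stood at -3.72. Between it and St6galnac2, 1810032O08Rik differed less, from 14.7 to 3.66 CPM (-2.01, and -0.98 with curdlan), and Gm11744, at low levels, by -2.77. BC018473 (116752167 to 116759373), annotated as antisense, lay at 328 and 0.874 CPM, a value that is uncertain because the libraries are unstranded. The flanking genes Rhbdf2 (1.20) and Jmjd6 (0.48) were higher and Mxra7 (-1.82) was lower.

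Genes with at least 4-fold differences between the genotypes in both states numbered 588, of which 221 were higher and 367 lower in the libraries labelled KO. Of these, 388 with coordinates and outside the immunoglobulin and T cell receptor genes were counted in 1239 windows of 2 Mb, a choice made after seeing the data. Of these windows 8 passed, and the 4 with the smallest p are given. The first lay on chromosome 19 from 34 Mb, where 7 of 17 tested genes included Ifit1, Ifit2, Ifit3 and Ch25h (one-sided binomial test with Benjamini-Hochberg adjustment, adjusted p = 5.2e-05). On the same chromosome from 10 Mb, 10 of 48 genes included 7 of the Ms4a family (adjusted p = 5.36e-05). On chromosome 1 from 88 Mb, 6 of 19 genes included Ugt1a8, Ugt1a9 and Ugt1a10 (adjusted p = 0.00104), and on chromosome 8 from 2 Mb, 6 of 25 included Cd209a, Cd209b, Cd209c, Cd209d and Cd209e (adjusted p = 0.00452). Members of such families share sequence, so these counts are not of independent genes.

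Ighg1 levels in WT varied with the replicate number. They measured 83.7, 96 and 36.3 CPM in unstimulated WT libraries 1, 2 and 4, and 83.7, 97.1 and 37.7 CPM in the curdlan libraries of the same numbers.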
